A study of Talinum fruticosum with 24 samples.

How the data were processed

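The 24 libraries came from leaves of 2-month-old plants, with 2 plants per combination of treatment (mock or 200 µM ABA) and harvest time (40, 80, 160, 320, 640 or 1280 min). Per the labels' protocols, polyadenylated RNA was made into strand-specific libraries with a TruSeq kit and sequenced as single reads of 150 bp on an Illumina HiSeq instrument, with 12 samples per lane. Which samples shared a lane is not given in the sources used here, so no batch could be examined. The series record states that conditions and replicates were corrected after the first deposit, and the corrected labels were used.

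The deposited values are whole-number counts of reads per feature, 1 list per library, with no normalisation. Features without reads in a library are not listed in it and were taken as 0 counts. The submitters' processing notes name CASAVA, Trimmomatic and DESeq2, without versions or roles. The aligner or counting tool, the reference sequences, the treatment of reads that match several features and the use of strand in counting are not given in the sources used here. Counts of near-identical or overlapping features may therefore be split between them. Whether the reference came from this species is not known here either. A feature may therefore hold reads of several transcripts, and other transcripts may be missed. Any single feature named in the text carries these uncertainties. The lists for replicate 2 of both treatments at 320 min are equal in size, so their contents were compared: 1.64% of features had identical counts and the log2 counts correlated at r = 0.9416 across features, so both were kept.

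Feature identifiers in the files are not paired with gene names, and no table of names was used. The 26 lists of 433 genes fixed before the data were examined (hormone signalling, carboxylation, malate transport, starch, clock and other classes) matched 0 identifiers. The planned tests of gene lists and the planned report on individual genes of those lists were therefore not run. Named features follow the remaining part of the rule set before the data were examined: in each comparison, the 2 that rose most and the 2 that fell most by log2 fold change. Each had to pass the threshold, have a mean of at least 10 counts over the 24 libraries, and have both ABA libraries on the same side of both mock libraries. For the average over harvests this order had to hold in at least 5 of the 6 harvests.

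Counts were analysed in R 4.3.3 with edgeR 4.0.16. Features were kept with edgeR's expression filter by group (minimum count 10), which left 17561 and removed 3056. Library composition was corrected with TMM factors, which ran from 0.66 to 1.70. A quasi-likelihood model with robust spread estimates was fitted to all 24 libraries with 1 mean for each of the 12 groups, leaving 12 residual degrees of freedom. All quoted tests are two-sided quasi-likelihood F-tests with Benjamini-Hochberg adjustment over the tested features and a threshold of 0.05. The comparisons were ABA against mock at each harvest, their average, the difference of the ABA effect between harvests (interaction) and the differences among mock harvests. The common biological coefficient of variation was 15.7%. Since groups of 2 against 2 separate completely for 33.3% of features by chance, separation alone was not used as evidence. The share observed was 32.9% at 40 min and 70.3% at 1280 min.

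Fold changes are given as log2 values with standard errors (SE). Each SE is the size of the log2 fold change divided by the square root of its quasi-likelihood F value. It therefore restates the F-test and is not a separate measure of spread. Ratios of counts pooled over all harvests are given with an exact 95% counting interval. Where 1 group had 0 counts, the bound uses a floor of 3 counts over the group, and where it had 1 to 3 counts the ratio is given with an exact 95% counting interval. Counts of features with at least 2-fold or 8-fold change use the same bound. Such intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. With totals of 16577222 to 26846579 counts, between 18389 and 19030 features were detected per library. Set tests used camera in limma 3.58.1 with a preset correlation of 0.01 and with an estimated one. Where lists of responding features were compared, the size of overlap for independent lists is the product of the list sizes divided by the 17561 tested features.

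The fit was tested on simulated counts for the same 17561 features with known changes. For ABA against mock at 320 min it recovered 19.4% of 1.5-fold, 62.7% of 2-fold and 93.9% of 4-fold changes, and 21 of 258 calls (8.1%) were false. For the average over harvests it recovered 91.0%, 97.0% and 100.0%, with 4 of 222 calls false. For the interaction, with changes placed only in ABA leaves at 320 min, it recovered 0% of 1.5-fold, 13.4% of 2-fold and 75.8% of 4-fold changes. Only small sets of simulated features were changed, none of them with low mean counts, and all others kept 1 mean over all groups. Features with few counts are therefore not covered by these rates. In the real counts 25.8% of features passed the threshold at 320 min and 80.5% between mock harvests, so these rates may not hold there.

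Alternatives fixed before the data were examined were DESeq2 1.42.0, other size factors, other filters, stricter thresholds, a replicate block, fits to single harvests, and leaving out each library in turn, both 320 min libraries of replicate 2, or the 40 and 80 min harvests from the average. Chosen after seeing the data were the group of abundant features with its sizes of 50, 100 and 200, the fit without that group, the thinning of all libraries to the smallest total, and the extension of the alternatives to that group, to the early risers, to the feature that fell at 40 min, to the steps between mock harvests and to the peaks of the mock course.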

Results

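Leaves of the waterleaf Talinum triangulare (also named Talinum fruticosum) were sampled after spraying with abscisic acid (ABA), the plant hormone of the drought response, or with a mock solution. The species can switch from ordinary C3 photosynthesis to crassulacean acid metabolism (CAM), in which carbon dioxide is taken up at night and stored as malic acid. The design asks which leaf transcripts change early after ABA and how the response develops over the following day. Leaves received 200 µM ABA or mock solution 4 h into a 12 h light period, and a second spray followed 4 h later. Harvests followed at 40, 80 and 160 min and again at 320, 640 and 1280 min, counted from the first spray. The first 4 harvests fell in the light period, the 640 min harvest fell 2.7 h into the night, and the 1280 min harvest fell 1.3 h into the next light period. Each of the 12 groups held 2 libraries, each from a different plant with its 2 treated leaves pooled. Library totals ran from 16577222 to 26846579 counts, with 21282964 ± 2286662 in ABA libraries and 21730387 ± 2733455 in mock libraries (SD, n = 12 each). Counts were found for 20617 features in at least 1 library, and 17561 features were tested. Levels are given as CPM, counts scaled to a common library total after TMM correction for composition. The files used here do not pair feature identifiers with gene names, so features are described by their behaviour, and only a few identifiers are given for each comparison.

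Harvest time was the main axis along which the leaf transcriptomes separated, and ABA leaves lay further from mock leaves at later harvests. The harvests from 320 min on also followed the second spray, and time of day changed with every harvest. Growth of the ABA response up to 160 min came before the second spray, but there elapsed time and time of day cannot be told apart. From 320 min on, the second spray cannot be told apart from them either. At 40 min the 4 libraries lay together, with scores on the second principal component from -59.4 to -51.9. At 1280 min mock libraries scored 42.5 and 48.3 on that component, and ABA libraries scored 111.2 and 128.8. The first component held 36.4% of the variance and the second 25.4%. Replicates correlated at r between 0.9713 (ABA, 1280 min) and 0.9909 (mock, 320 min) across features, which are not independent of each other. Each library was counted as a separate sample, since each came from a different plant. Replicate pairs differed by more than sampling noise (chi-square per degree of freedom of at least 5.45), which has no bearing on that choice.

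**Figure D1:**
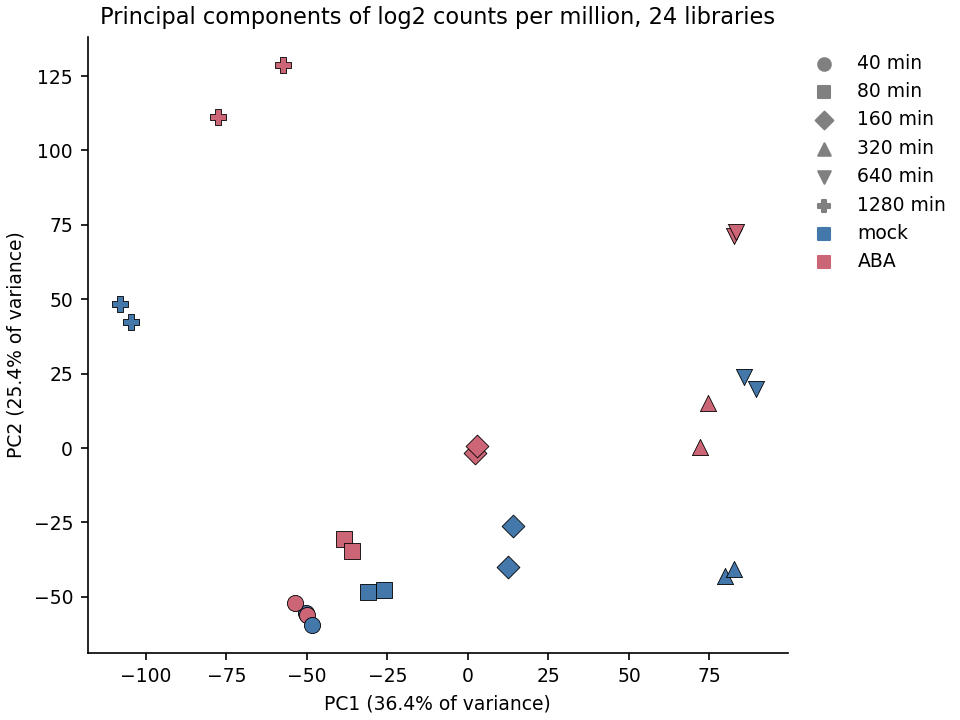
Scores of the 24 libraries on the first principal component (x axis, 36.4% of variance) and the second (y axis, 25.4%), from log2 CPM, with colour for treatment and marker shape for harvest time. The 4 libraries of 40 min lie together, and at 1280 min the ABA libraries score 111.2 and 128.8 on the second component against 42.5 and 48.3 for mock.

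At 40 min the response to ABA was small and, in the main fit, almost wholly an increase: 22 features were higher in ABA leaves and 1 was lower. KMS96920 rose most, from 0.242 ± 0.189 to 6.67 ± 0.637 CPM (SD, n = 2 per group), a log2 fold change of 4.81 ± 0.47 (SE; edgeR adjusted p = 1.81e-05). Its mock libraries held 6 and 2 counts, and the log2 fold change was 5.88 without mock replicate 1 and 4.13 without mock replicate 2. KMT04465 rose from 0.462 ± 0.0339 to 6.87 ± 2.16 CPM, a log2 fold change of 3.88 ± 0.52 (SE; edgeR adjusted p = 0.0013). Both were also higher in ABA leaves at each of the other 5 harvests. The feature that fell, KMT06910, had 9 and 9 counts in the mock libraries and 0 and 0 in the ABA libraries, at least 5.7-fold lower with ABA (floor of 3 counts over the group; edgeR adjusted p = 0.0176). It was named after its values were seen, since its mean of 5.2 counts lies under the limit for named features. Its call was lost in 6 of 36 alternatives: adjusted p = 0.104 without mock replicate 1, 0.269 without ABA replicate 1, 0.376 without ABA replicate 2, 0.299 with a replicate block within harvests, 0.059 without both second libraries of 320 min, and the stricter threshold of 0.01. In 2 others it was not tested, and DESeq2 gave it no adjusted p, so the single decrease is a weak call. Adjusted p ran from 0.0176 to 0.376 over these alternatives, applied to this feature after seeing the data.

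The 22 early risers formed a lasting group. All 22 were also higher in ABA leaves at 80 min and at 160 min, where the group means come from other plants but the estimate of spread was shared by all harvests, then 19 at 320 min, 20 at 640 min and 15 at 1280 min, when 2 were lower. Their median log2 fold change was 1.73 at 40 min, 3.09 at 80 min, 2.71 at 160 min, 2.43 at 320 min, 2.33 at 640 min and 1.16 at 1280 min. For 19 of the 22 the ABA effect differed between harvests by the interaction test. The number of features past the threshold at 40 min was 41 without mock replicate 2 (20 higher and 21 lower), 58 with a fit to the libraries of that harvest alone and 49 with DESeq2, which shared 22 of the 23. Without mock replicate 1 at 40 min, KMT04465 had an edgeR adjusted p of 0.0502, within a range of 1.78e-11 to 0.0502 over its alternatives.

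**Figure D2:**
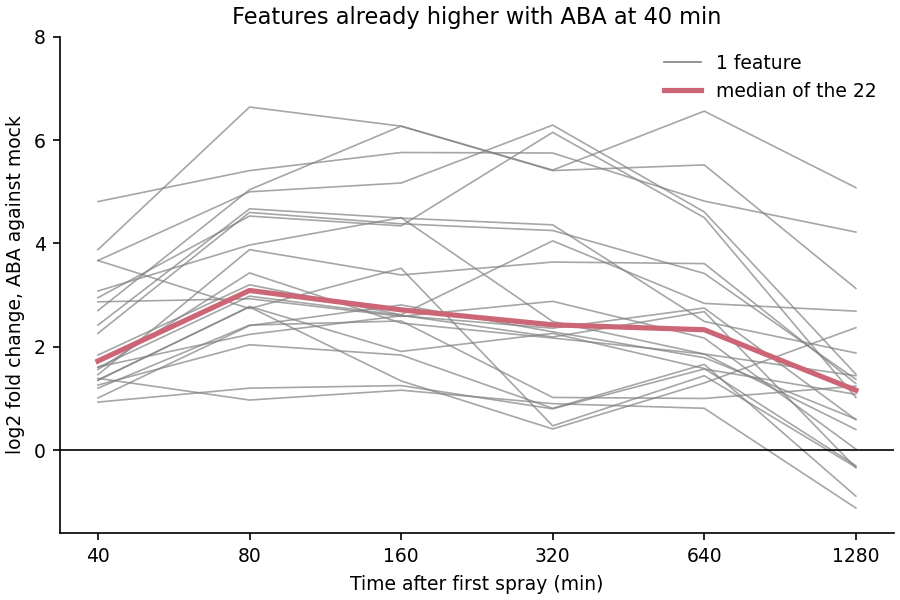
Log2 fold change of ABA against mock leaves (y axis) at each harvest (x axis, minutes after the first spray) for the 22 features higher with ABA at 40 min, with 1 thin line per feature and the median as the thick line. The median is 1.73 at 40 min, 3.09 at 80 min and 1.16 at 1280 min.

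By 80 min, 1039 features differed, 716 higher and 323 lower with ABA, and 361 of the higher and 126 of the lower ones changed at least 2-fold. KMT13960 had no counts in the mock libraries and 75 in the ABA libraries, at least 27.9-fold higher (edgeR adjusted p = 0.00132). KMT04465 rose to 46.6 ± 22.6 CPM against 0.454 ± 0.186 in mock leaves (SD, n = 2 per group), a log2 fold change of 6.64 ± 0.47 (SE; edgeR adjusted p = 1.28e-07). KMS99463 fell from 3.33 ± 0.00727 to 0.162 ± 0.139 CPM, a log2 fold change of -4.25 ± 0.70 (SE; edgeR adjusted p = 0.00113). Its ABA libraries held 5 and 1 counts, and the log2 fold change was -5.6 without ABA replicate 1 and -3.65 without ABA replicate 2. KMS98552 had 1 count with ABA and 45 in mock leaves, a ratio of 0.0248 (95% counting interval 0.000614 to 0.145; edgeR adjusted p = 0.0485). That last call was lost in 20 of 35 alternatives, whose adjusted p ran from 0.014 to 0.253. The total was 1683 without mock replicate 1, 494 without mock replicate 2, 566 without ABA replicate 2, and 313 in a fit to the libraries of that harvest alone.

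At 160 min the response had grown to 2390 features, 1501 higher and 889 lower, still tilted towards increases. KMS96215 had 0 counts in mock leaves and 155 with ABA, at least 43.7-fold higher (edgeR adjusted p = 2.38e-05). KMT08628 had 0 counts in mock leaves and 238 with ABA, at least 67.2-fold higher (edgeR adjusted p = 0.0127). Its mock libraries varied at other harvests, with 65 and 0 counts at 80 min, and its adjusted p was 0.0756 without mock replicate 1, 0.106 without mock replicate 2 and 0.0573 without ABA replicate 2, within a range of 0.000134 to 0.106 over its alternatives. KMT03949 fell from 3.78 ± 1.60 to 0.0999 ± 0.141 CPM (SD, n = 2 per group), a log2 fold change of -5.02 ± 0.74 (SE; edgeR adjusted p = 0.000131). Its ABA libraries held 5 and 0 counts, and the log2 fold change was -4.2 without ABA replicate 2. Without ABA replicate 1 the ABA count was 0, so only a bound could be given. KMS99463, already lower at 80 min, was lower again, by a log2 fold change of -4.88 ± 0.75 (SE; edgeR adjusted p = 0.000262). That value was -5.97 without ABA replicate 2 and -4.13 without ABA replicate 1. Of the 716 features higher at 80 min, 466 were higher at 160 min, against 61 for independent lists. The total was 1552 without ABA replicate 1, 1287 without ABA replicate 2 and 1194 without mock replicate 2.

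At 320 min, 80 min after the second spray, increases and decreases were close in number: 2391 features were higher and 2143 lower with ABA. KMS96215 stayed without counts in mock leaves and had 136 with ABA, at least 38.4-fold higher (edgeR adjusted p = 2.19e-05). KMT07654 had 0 counts in mock leaves and 58 with ABA, at least 16.4-fold higher (edgeR adjusted p = 0.00347). The ABA libraries held 12 and 46 of these counts, so the bound rests mostly on ABA replicate 2. KMT00441 fell from 3.32 ± 0.716 to 0.124 ± 0.00798 CPM (SD, n = 2 per group), a log2 fold change of -4.67 ± 1.01 (SE; edgeR adjusted p = 0.00301). KMT12396 had 3 counts with ABA and 70 in mock leaves, a ratio of 0.0363 (95% counting interval 0.0073 to 0.11; edgeR adjusted p = 0.000165). The total of 4534 was 2229 without ABA replicate 2, 2429 without mock replicate 1, 2801 without mock replicate 2 and 1203 without replicate 2 of both treatments, a setting that also ended the calls of KMT07654 (adjusted p = 0.154) and KMT00441 (adjusted p = 0.0724). Scaling to library size alone gave 3784 higher and 1093 lower, 77.6% higher in place of 52.7%, and moved the median log2 fold change of all features from 0.00 to 0.26.

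In the night, at 640 min, 1962 features were higher and 2381 lower in ABA leaves, a tilt whose direction depended on the setting. KMT06401 had 1035 counts with ABA and 2 in mock leaves, a ratio of 447 (95% counting interval 124 to 3700; edgeR adjusted p = 3.13e-06). KMS96215 had 107 counts with ABA and 0 in mock leaves, at least 30.8-fold higher (edgeR adjusted p = 4.23e-05). KMT00441 had 0 counts with ABA and 86 in mock leaves, at least 33.2-fold lower (edgeR adjusted p = 0.00285). The mock libraries held 21 and 65 of these counts, so the bound rests mostly on mock replicate 2. KMT09520 fell from 4.29 ± 0.977 to 0.0901 ± 0.0419 CPM (SD, n = 2 per group), a log2 fold change of -5.48 ± 0.71 (SE; edgeR adjusted p = 2.7e-05). The total of 4343 was 2441 without mock replicate 1, 2699 without ABA replicate 1 and 2808 without ABA replicate 2. With library size alone the direction of the tilt turned, to 2893 higher and 1450 lower (66.6% higher in place of 45.2%), with a median of all features of 0.20 in place of -0.02. Leaving out the 100 most abundant features at 40 min, an alternative chosen after seeing the data, also turned it, to 2220 higher and 2094 lower (51.5% higher).

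At 1280 min, in the next morning, 7983 features (45.5% of those tested) differed, 4092 higher and 3891 lower. This was the highest count of the 6 harvests in the fit to all libraries, while fits to single harvests gave 5544 features at 1280 min and 5510 at 640 min. At least 2-fold changes were seen in 2003 of the higher and 2350 of the lower features, and at least 8-fold changes in 266 and 203. KMT18510 fell from 54.0 ± 1.12 to 0.269 ± 0.134 CPM (SD, n = 2 per group), a log2 fold change of -7.60 ± 0.44 (SE; edgeR adjusted p = 1.13e-09). KMT00662 fell from 71.9 ± 3.93 to 0.408 ± 0.453, a log2 fold change of -7.41 ± 0.55 (SE; edgeR adjusted p = 2.45e-08). The ABA libraries held 18 and 2 counts of KMT00662, and its log2 fold change was -9.59 without ABA replicate 1 and -6.61 without ABA replicate 2. At 40 min the same 2 features had log2 fold changes of -0.36 ± 0.28 and -0.19 ± 0.37, neither past the threshold, and their ABA effects differed between harvests (interaction, edgeR adjusted p = 9.39e-07 and 1.65e-05). Among the features that rose, KMT03234 had 138 counts with ABA and 0 in mock leaves, at least 29.7-fold higher (edgeR adjusted p = 1.65e-05), and KMT15324 had 89 and 0, at least 19.2-fold higher (edgeR adjusted p = 0.000102). Scaling to library size alone gave 9262 higher and 1692 lower, 84.6% higher in place of 51.3%, with a median of all features of 0.74 in place of 0.06. Directions in this and the other comparisons are relative to the TMM scaling.

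**Figure D3:**
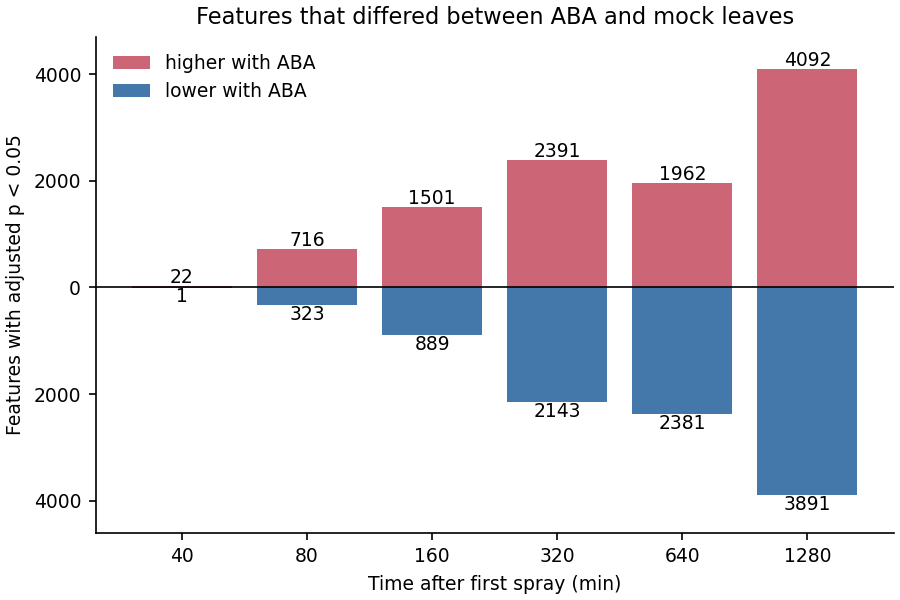
Number of features past an edgeR adjusted p of 0.05 (y axis) at each harvest (x axis, minutes after the first spray), with those higher in ABA leaves drawn above 0 and those lower below 0. Higher and lower features number 22 and 1 at 40 min and 4092 and 3891 at 1280 min; with scaling to library size alone the 1280 min split is 9262 and 1692.

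Averaged over the 6 harvests, 3991 features were higher and 3914 lower with ABA. Ratios in this paragraph pool the counts of the 12 libraries of each treatment. Each adjusted p tests instead the average of the 6 log2 fold changes, with every harvest weighted alike. KMS96215 had 761 counts over the 12 ABA libraries and 3 over the 12 mock libraries, a ratio of 222 (95% counting interval 75.6 to 1080; edgeR adjusted p = 1.03e-08). KMT13960 had 338 and 5 counts (edgeR adjusted p = 4.56e-07). KMS99463 had 51 against 523, a ratio of 0.0852 (95% counting interval 0.0626 to 0.114, edgeR adjusted p = 1.15e-06). KMT00441 had 84 counts with ABA against 609, a ratio of 0.121 (95% counting interval 0.0948 to 0.152, edgeR adjusted p = 8.75e-06). Their fitted averages, log2 fold changes of -3.79 ± 0.42 and -3.68 ± 0.46 (SE), carry no bound. Each includes a harvest with 0 ABA counts, 1280 min for KMS99463 (at least 3.1-fold lower) and 640 min for KMT00441 (at least 33.2-fold lower). With library size alone the split was 7537 higher and 2085 lower, 78.3% higher in place of 50.5%, with a median of all features of 0.21 in place of 0.00.

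**Figure D4:**
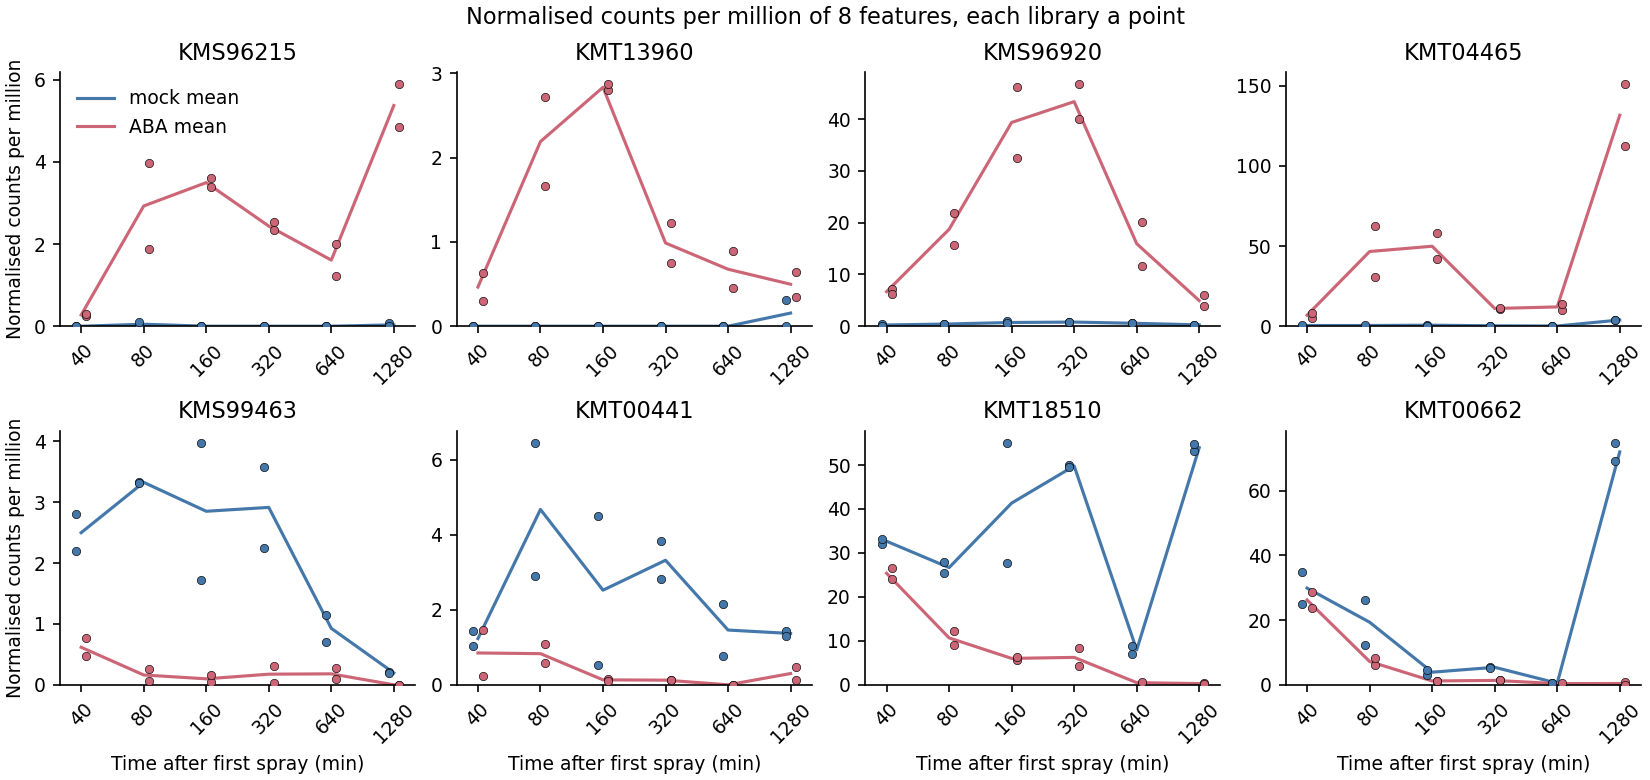
Normalised CPM (y axis, a separate scale in each panel) at each harvest (x axis, minutes after the first spray) for 8 named features, with points for single libraries and lines for the means of 2. KMS96215, KMT13960, KMS96920 and KMT04465 are higher in ABA leaves; KMT18510 reaches 54.0 ± 1.12 in mock and 0.269 ± 0.134 in ABA leaves at 1280 min (SD, n = 2 per group).

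Many features responded at several harvests, and others were first called late. In all, 10689 features passed the threshold in at least 1 harvest, and 3482 of them first did so at 1280 min. Of the features higher at 320 min, 1139 were higher at 640 min against 267 for independent lists, and of those lower, 1281 were lower again against 291. From 640 to 1280 min, 1075 higher features and 1603 lower features were shared, against 457 and 528. The group means of different harvests came from different libraries, but each feature had 1 estimate of spread for all harvests, so a feature with a low estimate is more easily called at several harvests and the overlap for independent lists is only a rough reference. A set of 183 features was higher in at least 5 harvests, 14 of them in all 6, and 52 features were lower in at least 5. The effect of ABA differed between harvests for 6388 features (36.4%) by the interaction test. This included 815 of the 819 features that were higher at 1 harvest and lower at another, which opposite calls from the same fit nearly guarantee. Of the 819, 242 were higher at 320 min and lower at 1280 min and 192 the reverse, 434 opposite calls against 1029 for independent lists.

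Few of the most abundant features were lower with ABA at 160 min, and most were at 1280 min. The 100 features with the most counts in the 4 libraries of 40 min, a group formed after the data had been seen, held 50.1% ± 3.2 of mock counts and 47.4% ± 0.6 of ABA counts at 40 min (SD, n = 2 per group). At 1280 min they held 40.8% ± 1.5 in mock and 21.5% ± 6.6 in ABA leaves, with 26.2% in ABA replicate 1 and 16.8% in replicate 2 (Wilson 95% intervals 26.17 to 26.20 and 16.83 to 16.86, for counting error only). Of the 100 features, 3 were lower at 160 min (97 not past the threshold), 43 were lower and 1 higher at 320 min (56 not past the threshold), 61 and 1 at 640 min (38 not past it), and 72 and 1 at 1280 min (27 not past it), with median log2 fold changes of -0.57, -1.19 and -2.04. Scaling to library size alone gave 34, 61 and 60 lower features and medians of -0.31, -0.96 and -1.37. Among the next 900 features by abundance, 449 were lower and 150 higher at 1280 min, while beyond rank 5000, 2013 were lower and 2952 higher. As a set tested against all other features, camera gave an adjusted p of 0.606 at 80 min, 0.0269 at 160 min, 6.43e-14 at 320 min, 2.05e-23 at 640 min and 2.66e-24 at 1280 min with its preset correlation, but adjusted p = 0.917, 0.805, 0.24, 0.15 and 0.15 with an estimated correlation, so that the set call was lost. The 43 lower features at 320 min were 14 without ABA replicate 2, 23 without mock replicate 1, 28 without mock replicate 2 and 6 without replicate 2 of both treatments.

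**Figure D5:**
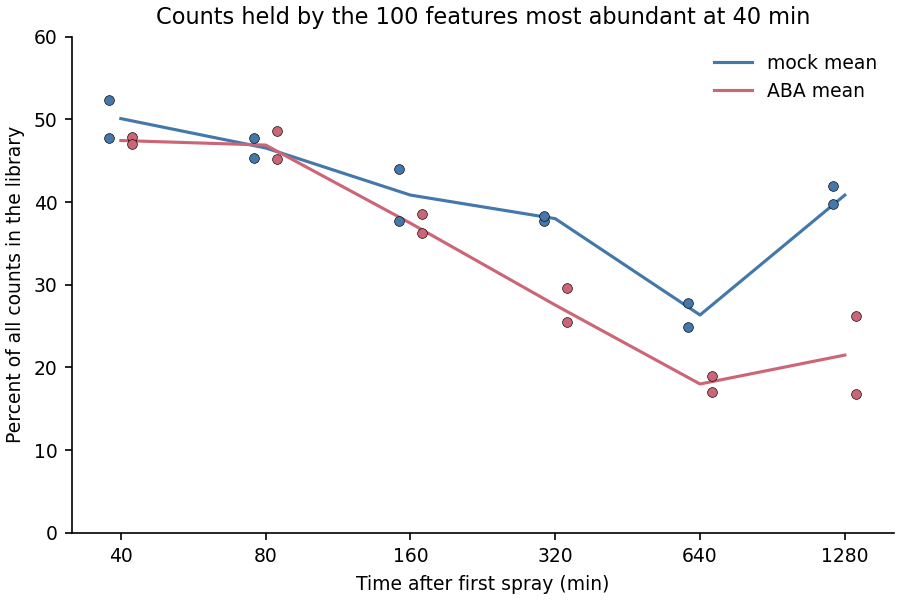
Percent of all counts in a library (y axis) held by the 100 features most abundant at 40 min, at each harvest (x axis, minutes after the first spray), with points for single libraries and lines for the means of 2. Mock and ABA means are 50.1% and 47.4% at 40 min and 40.8% and 21.5% at 1280 min, where the ABA libraries hold 26.2% and 16.8%.

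Mock leaves changed widely over the same day, which sets the background for the ABA response. The abundance of 14138 features (80.5%) differed between mock harvests. Among these, 11165 ranged at least 2-fold and 2308 at least 8-fold between the highest and lowest mock mean, on a log2 scale with a prior count of 2. The largest class, 4473 features, peaked at 1280 min, followed by 2941 at 320 min and 2831 at 640 min. This ranking depended on the scaling: with library size alone, an alternative chosen after seeing the data, 7070 peaked at 640 min, 2580 at 1280 min and 2024 at 320 min, and 12502 and 2747 ranged at least 2-fold and 8-fold. Between the night harvest at 640 min and the next morning at 1280 min, 10305 features changed in mock leaves, more than the 7983 that separated ABA from mock leaves at 1280 min. That step held 4847 higher and 5458 lower features, while scaling to library size alone gave 2046 higher and 10673 lower (16.1% higher in place of 47.0%), with a median of all features of -0.99 in place of -0.07. Time after spraying and time of day rise together in this design, so the mock time course holds both. Changes of the ABA effect between harvests hold both as well, together with the second spray for harvests from 320 min on.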

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

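Of the tests in this part, those on the 100 most abundant features (the comparison with all others under scaling, the share taken up by the largest gainers and the comparison of totals) were chosen after the pattern was seen, as was the test of admixture in ABA replicate 1, and the comparisons under scaling and of totals were chosen after their own results were seen. The effect of ABA differed between harvests for 6388 features, a result singled out because it compares the same contrast across times. 5 named features also passed that test, with interaction adjusted p (edgeR) of 0.0265 for KMT08628, 0.0188 for KMT12396, 0.028 for KMT15324, 9.39e-07 for KMT18510 and 1.65e-05 for KMT00662. KMT08628 and KMT15324 were named as rising and the other 3 as falling with ABA. All 5 were chosen for a large change at a single harvest, which favours passing the interaction test. Groups of 2 are too small for a test of outlying samples.

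For the average over harvests, 40 relabellings of ABA and mock within harvests were examined, the real one included, and 1 of the 40, the real one, gave as many as 7905 features. The highest of the others gave 6836 and the median of the others was 4. A relabelling that puts ABA and mock libraries in 1 group widens the estimated spread, which lowers its count. With 40 relabellings, 1 in 40 is also the lowest share possible, so the comparison does not exclude a chance assignment of labels. The relabelling with 6836 kept 20 of the 24 real labels, among them all 12 of the harvests from 320 min on, and the next highest gave 2193.

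The lower level of most of the 100 most abundant features at 1280 min was set against 3 technical explanations. A scaling factor moves all features alike, but the median log2 fold change of the 100 lay -2.10 from that of all other features (-2.04 against 0.06). Uptake of reads by a few strongly induced features is argued against by the shares: the 100 features lost 19.3 percentage points of counts, and the 10 largest gainers took up 16.1% of that loss. The 1000 largest gainers together gained 19.4 points, so uptake by many features is not argued against. As for depth, the ABA libraries of 1280 min held 97% of the mock total on average (19959396 ± 2673035 against 20572700 ± 42112 counts, SD, n = 2 per group). Mean totals were thus close, but a total does not by itself move a share of counts, so the comparison is no test of the lower share. A lower abundance of these transcripts in ABA leaves and a rise of many others are the hypotheses left open, since counts give shares only. Lane effects were not tested, since the labels do not give lanes.

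At 1280 min, ABA replicate 1 lay between mock leaves and ABA replicate 2. The root mean square log2 fold change of called features was 1.41 in replicate 1 and 1.72 in replicate 2, and 72.1% of them changed more in replicate 2. A like imbalance was seen at 320 min (1.17 against 1.5, 76.8% larger in replicate 2) and, among 23 features, at 40 min (78.3%), but little or none at 80 min (54.6%), 160 min (58.1%) and 640 min (50.1%). Admixture of RNA from mock leaves at 1280 min would have to be about 38.9% of the library, judged from the share of the abundant features, but for 13 features under 2% of the mock level in ABA replicate 2, the median level in ABA replicate 1 was 3.71% of mock, which argues against such a mixture. A difference between the plants in the size or the timing of the response may remain, and with 2 plants it was not tested.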

How the results depend on the processing

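The group of abundant features and its alternatives were chosen after seeing the data. Of the alternative values for the 9 counts of features that answer a comparison (the steps between mock harvests left out), 291 were within 1.5 times the original count and 28 were not. For a single harvest, most settings without 1 library left out a library of another harvest. Every such setting beyond 1.5 times left out a library of the harvest in question, so the 291 overstate the stability of single harvests. Of 917 alternative values for the 26 results on named features, 890 kept direction and call, 27 lost the call and 0 reversed. The named features were picked for large changes with both ABA libraries on the same side of both mock libraries. Leaving out a library could therefore hardly reverse them, and for a single harvest most such settings left out a library of another harvest. Settings in which a feature was not tested or had no adjusted p are not among the 917. A threshold of 0.01 gave 449 features at 80 min, 1316 at 160 min, 2649 at 320 min, 2647 at 640 min and 3888 for the interaction. Asking also for a 2-fold change by the fitted values gave 487, 1243, 1955, 2067 and 4358 features at 80, 160, 320, 640 and 1280 min. Both follow from the stricter rule itself. Scaling to library size alone gave 678 at 80 min, a fit to single harvests gave 58 at 40 min and 313 at 80 min, and DESeq2 gave 49 at 40 min, and in these the cause was not tested. Without both 320 min libraries of replicate 2 the count there was 1203, with 1 library left on each side.

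Leaving out 1 library at a time, with a lone library assumed to vary like the other groups, gave 17 to 41 features at 40 min, 494 to 1683 at 80 min, 1194 to 2729 at 160 min, 2229 to 4957 at 320 min, 2441 to 4776 at 640 min and 6010 to 8311 at 1280 min. The ranges were 7272 to 8245 for the average, 5108 to 7228 for the interaction and 13371 to 14456 for the mock harvests, and 8699 to 10596 for the mock step from 640 to 1280 min. The share of the 22 early risers higher at 80 min and at 160 min ran from 95.5% to 100% over the same settings. Counts beyond 1.5 times came without mock replicate 2 at 40 min (41); mock replicate 1 (1683), mock replicate 2 (494) or ABA replicate 2 (566) at 80 min; ABA replicate 1 (1552), ABA replicate 2 (1287) or mock replicate 2 (1194) at 160 min. At 320 min they came without mock replicate 1 (2429), mock replicate 2 (2801) or ABA replicate 2 (2229), and at 640 min without mock replicate 1 (2441), ABA replicate 1 (2699) or ABA replicate 2 (2808).

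Replicate numbers did not pair the samples: deviations of same-numbered ABA and mock libraries correlated at -0.10 to 0.10 across features. A replicate block within harvests gave 18, 764, 2051, 4130, 3864 and 7589 features from 40 to 1280 min, 7516 for the average and 5195 for the interaction. The mock time course could not be fitted with that block, which takes up the differences between harvests. One block over all libraries gave 23, 980, 2318, 4438, 4313 and 7923 features, then 7812, 6170 and 14052. Planned tests of gene lists were not run, since the lists matched 0 identifiers. In simulated counts with few changed features, 19.4% of 1.5-fold changes were recovered at 320 min. The real counts held many more changes, so the rate may differ there, but small changes can be missed with 2 plants per group.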

Other observations

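Both tests in this part were added after the data had been seen, and the comparison of ABA leaves with the preceding mock harvest was chosen after its result was seen. At 320 min, the difference of ABA from mock leaves correlated across 15112 features with that of the preceding mock harvest at 160 min (0.44 and 0.43, with the mock libraries split so that neither side shared one). It also correlated with that of the following mock harvest at 640 min (0.31 and 0.29), so the direction was not specific to the earlier harvest. A candidate explanation was that ABA leaves lag behind mock leaves in the daily course. It was taken to need a positive correlation with the preceding mock harvest at every harvest from 80 min on. The values were 0.01 and 0.09 at 80 min, 0.28 and 0.10 at 160 min, and 0.28 and 0.34 at 1280 min, but -0.23 and -0.15 at 640 min. At 640 min, with -0.15 as the larger value, ABA leaves did not differ towards the mock leaves of 320 min. Gaps between harvests grew, however, and a lag shorter than a gap would place ABA leaves at times without a mock harvest. The test therefore cannot decide whether ABA leaves lagged, over the whole course or at single harvests. A second hypothesis was that transcripts change less over the day in ABA leaves. The slope of the ABA time course on the mock time course was 0.712 (0.674 to 0.751 over the pairs of replicates), against 0.882 for 1 mock replicate on the other, a ratio of 0.81, as smaller changes would give. The spread over time was nearly alike, however, with a median SD of 0.50 in ABA and 0.53 in mock leaves (log2), and 42.1% of features varied more in ABA leaves. A course that differs in shape as well as in size may give the same slope, and these data do not separate the explanations further.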
